A study of Staphylococcus aureus with 2 samples.

How the data were processed

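Total RNA of Staphylococcus aureus USA300 Houston was measured at 3 h and 16 h of growth, with 1 library per time point. Per the labels' protocols, RNA was purified on columns, treated to remove DNA, depleted of ribosomal RNA and made into libraries with an Ion Total RNA-Seq kit. The deposited tables have 2649 gene rows and 303 small RNA rows, with positions on the chromosome of USA300 FPR per the file headers. The strain in the labels is USA300 Houston, so differences between these genomes could affect single rows. The aligner, its settings, the genome release and the use of strand are not given in the sources used here. Overlapping and antisense features therefore cannot be told apart with certainty.

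The deposited total and unique gene reads are raw counts per feature, per the file headers; total reads include reads that map to several places. The authors' RPKM values are reads scaled to feature length and to mapped reads, per the file headers. They rest on 3760998 mapped reads at 3 h and 3668319 at 16 h in the gene table, and on 3608889 and 3577098 in the small RNA table, as computed from the reads, lengths and RPKM. The deposited normalized expression values are a score without a stated method, per the file headers. The fold changes in the authors' deposited table are signed ratios of the RPKM or normalized values at 16 h against 3 h. The tables were made separately, so small RNA ratios were scaled with the coding rows of the gene table, and the 2 tables were not added.

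Of the gene rows, 2572 were taken as coding, 60 as short rows (under 100 nt with no symbol), 16 as ribosomal RNA and 1 as transfer-messenger RNA. A symbol was given for 917 coding rows, and the other 1655 have a locus identifier only. The reference gene table at hand is of another strain and matched 0 of these identifiers, so it was not used. Of the coding rows, 129 overlap a small RNA row, 68 by 50% or more of their length, and 42 lie wholly inside one; of these 42, 36 had at least 20 reads over both libraries and 5 had under 3 reads in each. The mapped reads of the gene table exceed the reads in its rows by 339567 and 1426022. Those numbers are 0.990 and 0.998 times the reads of the small RNA table less the ssrA row. How reads in bases shared by the 2 tables were counted is not given. The ssrA row holds 49.8% and 50.0% of the reads of the small RNA row at its position. A 135-nt coding row inside the small RNA beside agrB (2146572 to 2146706) holds 0 reads at 3 h and 1 read at 16 h, and was not compared.

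From the counts, ratios of scaled counts (CPM) were computed with TMM scaling over coding rows, trimming 30% of ratios and 5% of levels. The factor, 0.695 for 16 h over 3 h, was the same with edgeR 4.0.16 in R 4.3.3. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Rows needed at least 20 reads over both libraries, which left 2390 coding and 232 small RNA rows. A row counted as higher or lower at 4-fold, and no p-value was computed because genes are not replicates. Each ratio has an exact Clopper-Pearson 95% interval that covers counting error only, since reads are not independent molecules. A row with no read at 16 h was counted as lower, and its fold was bounded with a floor of 3 reads in that library, which is 2.01 CPM at 16 h. On simulated Poisson counts for these coding genes (2372 past the minimum), 100% of 50 genes made 8-fold higher, 94.0% of 50 made 8-fold lower, 100% of 50 made 16-fold higher and 2.00% of 50 made 2-fold higher were called at 4-fold. Of 2172 genes left alone, 0.140% were called. The intervals held the true fold for 95.7% of the genes left alone and for 88.0% to 96.0% in the groups of 50. The simulation has counting error only, so it gives no rate of false calls between 2 cultures. Only 200 genes were changed in it, so it also does not show how the scaling behaves where many more genes differ.

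Choices of groups, gene lists, thresholds and other settings were made before the data were examined. Of 46 lists, 33 had at least 3 members past the minimum and 4 had 1 or 2. The other 9 (prophage, transposases, hypothetical proteins and 6 lists of small RNAs and leaders) needed names or descriptions that the tables used here do not hold, and are void. Members were matched by symbol, so a list can hold a gene whose symbol has another meaning; in the list of secreted enzymes lipA, and in the adhesin list the map locus at 2028565, are of this kind. A list's median was placed among 10000 random lists of its size matched in 10 bins of mean expression, as a description of these libraries. Random lists were drawn as single genes, so the percentile of a list with runs of neighbouring genes can be too extreme. The correlation across genes used log2 of CPM plus 1.

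Genes were named by a fixed rule. It took the 10 genes with a symbol with the highest and the 10 with the lowest ratios, up to 4 members per list with the largest ratios in either direction, and the 6 highest and 6 lowest small RNAs. It also took the agr genes, RNAIII, sigB, asp23, sarA, rot, codY, ccpA and mgrA, and the 5 rows with the most reads per library. A few further list members were chosen after their values were seen: ddh, acnA, mqo, rocF, gudB, purB, guaA, guaB, lukD, lukE, scpA, scpB and the gap locus at 843347. Alternatives covered the scaling, the read minimum, the fold threshold, an added 0.5 read, the deposited RPKM and the authors' fold changes. Unique reads, and leaving out coding rows with 50% or more of their bases inside small RNA rows, were added after the data were seen.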

Results

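RNA was sequenced from a wild-type strain of Staphylococcus aureus, USA300 Houston, a member of a lineage known for methicillin resistance and community-acquired infection. The bacteria were grown in tryptic soy broth at 37 °C with shaking and sampled at 3 h, in exponential growth, and at 16 h, in stationary phase. The study set out to describe how the transcriptome adapts to stationary phase. Ribosomal RNA was depleted, and 1 library was sequenced per time point. Coding genes held 3263392 reads in the 3 h library and 1791252 reads in the 16 h library. A separate table of small RNAs held 376515 and 1587610 reads. With 1 library per group, no difference has a replicate check and no test between conditions was possible. Intervals are exact 95% binomial intervals on the reads of the 2 libraries and cover counting error only. Ratios are 16 h over 3 h, scaled by the trimmed mean of M-values (TMM) over coding genes, and positions are on the USA300 FPR chromosome used in the deposited tables.

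The first comparison asked which protein-coding genes differed between exponential and stationary phase. Among genes with a symbol, the 10 highest ratios included genes for gluconeogenesis, amino acid breakdown, purine synthesis and secreted proteins. pckA (1915442 to 1917034), which encodes the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, was 208-fold higher at 16 h (interval 171 to 257). murQ (225019 to 225915), which encodes an enzyme of N-acetylmuramic acid use, was 186-fold higher (142 to 248). hlgA (2542127 to 2543056), a gamma-haemolysin subunit, was 107-fold higher (73.7 to 162), and the lipase gene lip (2830473 to 2832515) was 80.9-fold higher (72.7 to 90.2). At the other end, adhE (171207 to 173816), an alcohol and aldehyde dehydrogenase of fermentation, was 38.8-fold lower (30.7 to 49.7), and plc (108993 to 109979), a secreted phospholipase, was 31.0-fold lower (21.1 to 47.6).

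Of 2390 coding genes with at least 20 reads over both libraries, 212 were at least 4-fold higher at 16 h, 296 were at least 4-fold lower and 1882 lay between. The 10 genes with a symbol and the highest ratios were fadE, pckA, murQ, purS, the ald locus at 1820330, putA, hlgA, purE, purK and lip. fadE, in a cluster with the fatty acid degradation gene fadD, had 1 read at 3 h and 184 at 16 h, a ratio of 482 with an interval of 85.4 to 19141, and it lies wholly inside a small RNA row. The 10 lowest were cidA, the ald locus at 1492510, the ilvA locus at 1491375, ltrA, adhE, plc, the nuc locus at 866215, pbuX, trpE and xpt. Where 2 or more loci share a symbol, they are named with their start, and which of them is the gene usually meant is uncertain. cidA, a holin-like gene linked to autolysis, had 291 reads at 3 h and 1 at 16 h, which made it 111-fold lower with an interval of 19.8 to 4402. cidB (2676429 to 2677118), beside cidA, went the other way and was 3.265-fold higher (2.91 to 3.66). xpt and pbuX, a xanthine phosphoribosyltransferase and a xanthine permease, were 23.6-fold (19.4 to 28.9) and 24.9-fold (21.7 to 28.7) lower. ltrA, with 252 and 2 reads, was 48.1-fold lower (13.2 to 399). Among the 1655 coding genes without a symbol, those with at least 20 reads over both libraries and a read in each were ranked. The 2 coding genes past the minimum with no read at 16 h have no finite ratio and were left out. The most extreme were SAUSA300_0174, which went from 18926 to 8 reads and was 903-fold lower (458 to 2092), and SAUSA300_0192, which was 140-fold higher (114 to 174). The files do not pair these identifiers with names.

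The balance between higher and lower genes depended on the scaling. With equal totals of coding reads it was 133 higher and 427 lower, with equal totals of all rows it was 110 and 521, and with the deposited RPKM 83 and 833. These scalings shifted the median log2 ratio of all coding genes by -0.52, -0.78 and -1.35, and each moved every gene by the same amount. A log2 ratio above 0 and below that size is therefore below 0 in RPKM, while the order of genes and their distance from the median gene are as given here. A gene needed a log2 ratio of 3.35 here to be 4-fold higher in RPKM. The normalized fold changes in the authors' deposited table did not move every row alike. In the 10% of coding genes and of small RNAs with the highest levels, the log2 values in the authors' deposited table were lower than those given here by a median of 0.671 and 1.28. Where they end a 4-fold call of a gene or small RNA named here they are given with it, as are some of the larger other differences.

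**Figure D1:**
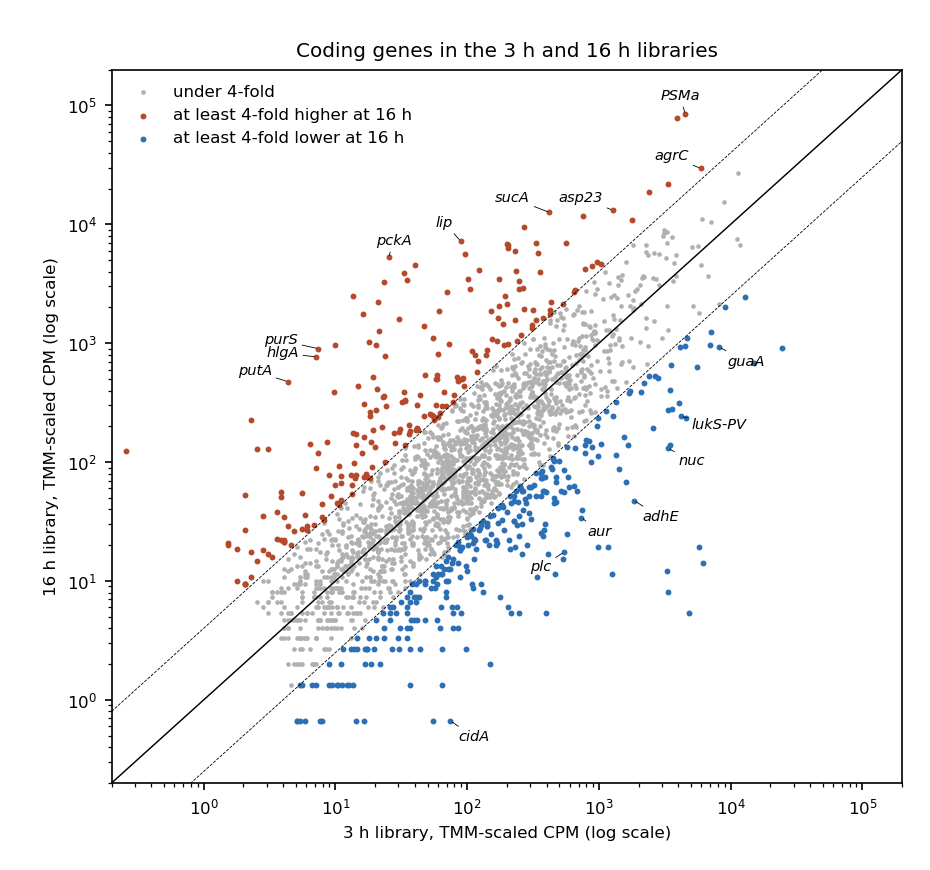
Each point is a coding gene with at least 20 reads over both libraries, at its TMM-scaled CPM (reads scaled to a common library size) in the 3 h library (x axis, log scale) and the 16 h library (y axis, log scale). The solid line marks equal values and the dashed lines mark 4-fold; 212 genes lie above and 296 below the dashed lines, of which 2 with no read at 16 h are not drawn. In the deposited RPKM these numbers were 83 and 833.

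Central carbon metabolism was compared through gene lists fixed before the data were examined. Of 13 genes of the tricarboxylic acid (TCA) cycle, which oxidises acetyl-CoA, 11 were at least 4-fold higher at 16 h and none was 4-fold lower. Their median log2 ratio was 3.45 (2.10 in RPKM), at percentile 100 of 10000 random lists matched on expression. With each run of neighbouring genes counted once it was 3.20 over 8 units. The random lists hold single genes, so percentiles of lists with such runs, here and below, can be too extreme. sucB and sucA, for 2-oxoglutarate dehydrogenase, were 30.8-fold (28.6 to 33.1) and 29.9-fold (28.5 to 31.5) higher. icd, for isocitrate dehydrogenase, was 27.4-fold higher and gltA, for citrate synthase, 20.1-fold higher. acnA, for aconitase, had a log2 ratio of 1.15 (below 0 in RPKM), and the mqo locus at 2744110 one of -0.86. The list of gluconeogenesis and acetate use had 2 measured members, pckA and the acetyl-CoA synthetase gene acsA, which was 57.6-fold higher (45.3 to 74.3).

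The 12 genes of glycolysis had a median log2 ratio of -1.55 (percentile 0.07; -1.25 with each run of neighbouring genes counted once), with 4 at least 4-fold lower and 1 at least 4-fold higher. pgk, tpiA and pfkA were 7.17-fold, 5.74-fold and 5.51-fold lower (13.6-fold, 12.8-fold and 7.53-fold in the authors' deposited table). The 1 higher member was a locus of gap, a symbol given to 2 loci that went opposite ways. Members were matched by symbol, so whether the higher locus acts in glycolysis is uncertain. The locus at 843347, beside pgk, was 5.25-fold lower (5.07 to 5.43) and the locus at 1787904 was 59.4-fold higher (47.7 to 74.8); the lowest share of their reads that mapped to 1 place was 99.9%. Of 10 genes of fermentation, 5 were at least 4-fold lower and 1, the lactate dehydrogenase gene ddh with a log2 ratio of 2.14, was at least 4-fold higher. The median was -2.28 (percentile 0.03). Besides adhE, adh was 19.6-fold lower and alsS, which makes acetolactate, 8.65-fold lower. nrdG, also 9.06-fold lower, belongs to anaerobic ribonucleotide reduction and not to fermentation itself. The 8 genes of ATP synthase had a median of 1.16 in TMM scaling and -0.20 in RPKM, and none differed by 4-fold. The 7 genes of nitrate and nitrite respiration had a median of -0.49 (percentile 32.4), with narI 4.18-fold higher (3.97-fold in the authors' deposited table) and narK 2.31-fold lower.

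The medians of the lists for breakdown and for synthesis of amino acids differed in sign. Of 25 genes of arginine, proline and glutamate catabolism, 10 were at least 4-fold higher at 16 h and 3 at least 4-fold lower, with a median log2 ratio of 1.87 (0.51 in RPKM, percentile 100). putA, for proline dehydrogenase, was 109-fold higher (67.8 to 189), and hutU, for urocanase in histidine breakdown, was 47.9-fold higher (38.2 to 60.9). rocF, for arginase, and gudB, for glutamate dehydrogenase, had log2 ratios of 4.32 and 4.06. ald, for alanine dehydrogenase, is the symbol of 2 loci; that at 1820330 was 113-fold higher (96.4 to 133) and that at 1492510 was 111-fold lower (69.3 to 191). The ilvA locus next to the latter was 60.3-fold lower (41.9 to 90.2). Of 20 genes of histidine, tryptophan and lysine synthesis, 9 were at least 4-fold lower and none was 4-fold higher, with a median of -1.54 (percentile 0.09). asd, for aspartate semialdehyde dehydrogenase, was 7.09-fold lower (5.16 to 10.01). trpE, trpD and trpG had 1 read each at 16 h and lie inside a small RNA row, so their ratios are uncertain; trpE was 24.4-fold lower with an interval of 4.23 to 980. Of 11 genes of branched-chain amino acid synthesis, 4 were at least 4-fold lower and none was 4-fold higher. The median was -1.53 (percentile 1.28), or -2.39 with each run of neighbouring genes counted once. The 4 were ilvE, 5.25-fold lower, ilvD, 5.59-fold lower, ilvN, and the ilvA locus next to ald at 1492510. ilvN was 10.1-fold lower on 53 and 2 reads, with an interval of 2.67 to 85.7. The ilvA locus at 2174333 had 81 and 28 reads and a log2 ratio of -0.14. Members were matched by symbol, so which ilvA locus acts in this synthesis is uncertain. The 7 urease genes had a median of 0.80 in TMM scaling and -0.55 in RPKM, with ureA 4.01-fold higher.

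Purine genes had the highest median of the 33 lists with at least 3 members, 5.05 (3.70 in RPKM, percentile 100). Many of them are neighbours, and with each run of neighbouring genes counted once the median was 2.92 over 4 units, below the 3.20 of the TCA cycle. Of 15 members, 12 were at least 4-fold higher at 16 h. purS was 121-fold higher (84.1 to 182), purE 105-fold (84.1 to 132), purK 97.2-fold (82.0 to 116) and purC 52.9-fold (44.0 to 64.1); all of these act before inosine monophosphate. purB had a log2 ratio of 1.92. guaB and guaA, which convert inosine monophosphate to guanosine monophosphate, were lower, each with a log2 ratio of -3.15. They lie in 1 stretch (436472 to 441388) with xpt and pbuX. The 11 pyrimidine genes had a median of 1.36 (percentile 99.8), 0.28 with each run of neighbouring genes counted once and 0.01 in RPKM, and none differed by 4-fold; carA and pyrC had the highest ratios, 3.45-fold and 3.07-fold.

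Genes of the growth machinery did not move as 1 group. The 20 genes of aminoacyl-tRNA synthetases, which charge transfer RNAs, had a median log2 ratio of -1.35 (percentile 0); 14 were at least 2-fold lower, 2 at least 4-fold lower and none 2-fold higher. leuS was 5.69-fold lower (4.94 to 6.59) and thrS 4.33-fold lower (3.98 to 4.72). The 54 ribosomal protein genes had a median of 0.46 (percentile 93.9), which became -0.04 in the authors' normalized values and -0.89 in RPKM, and 52 of them lay within 4-fold. rpmJ and rplA were 4.39-fold and 4.36-fold higher (2.88-fold and 2.85-fold in the authors' deposited table). The 12 translation factors had a median of 0.47 (-0.30 in the authors' normalized values, -0.88 in RPKM), with the release factor gene prfB 7.003-fold lower (5.62 to 8.83) and infB 3.48-fold higher. The 11 genes of RNA polymerase and its elongation factors had a median of 1.07 in TMM scaling (percentile 97.3) and -0.28 in RPKM, with nusA 4.82-fold higher. The 18 genes of DNA replication had a median of 0.05 and a mean of -0.01 (median -0.17 in the authors' normalized values, -1.30 in RPKM), with gyrB 4.02-fold higher (3.01-fold in the authors' deposited table) and topA 3.41-fold lower. The 27 genes of cell division and peptidoglycan synthesis had a median of -0.08, with pbpA 5.67-fold lower (4.95 to 6.53). The 13 fatty acid synthesis genes had a median of 0.36 (-0.29 with each run of neighbouring genes counted once, -0.35 in the authors' normalized values, -0.99 in RPKM). The accC locus at 1712836 was 8.68-fold higher on 89 and 295 reads. That at 1628768 was only 1.43-fold higher (1.30 to 1.58) on 1143 and 624 reads.

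**Figure D2:**
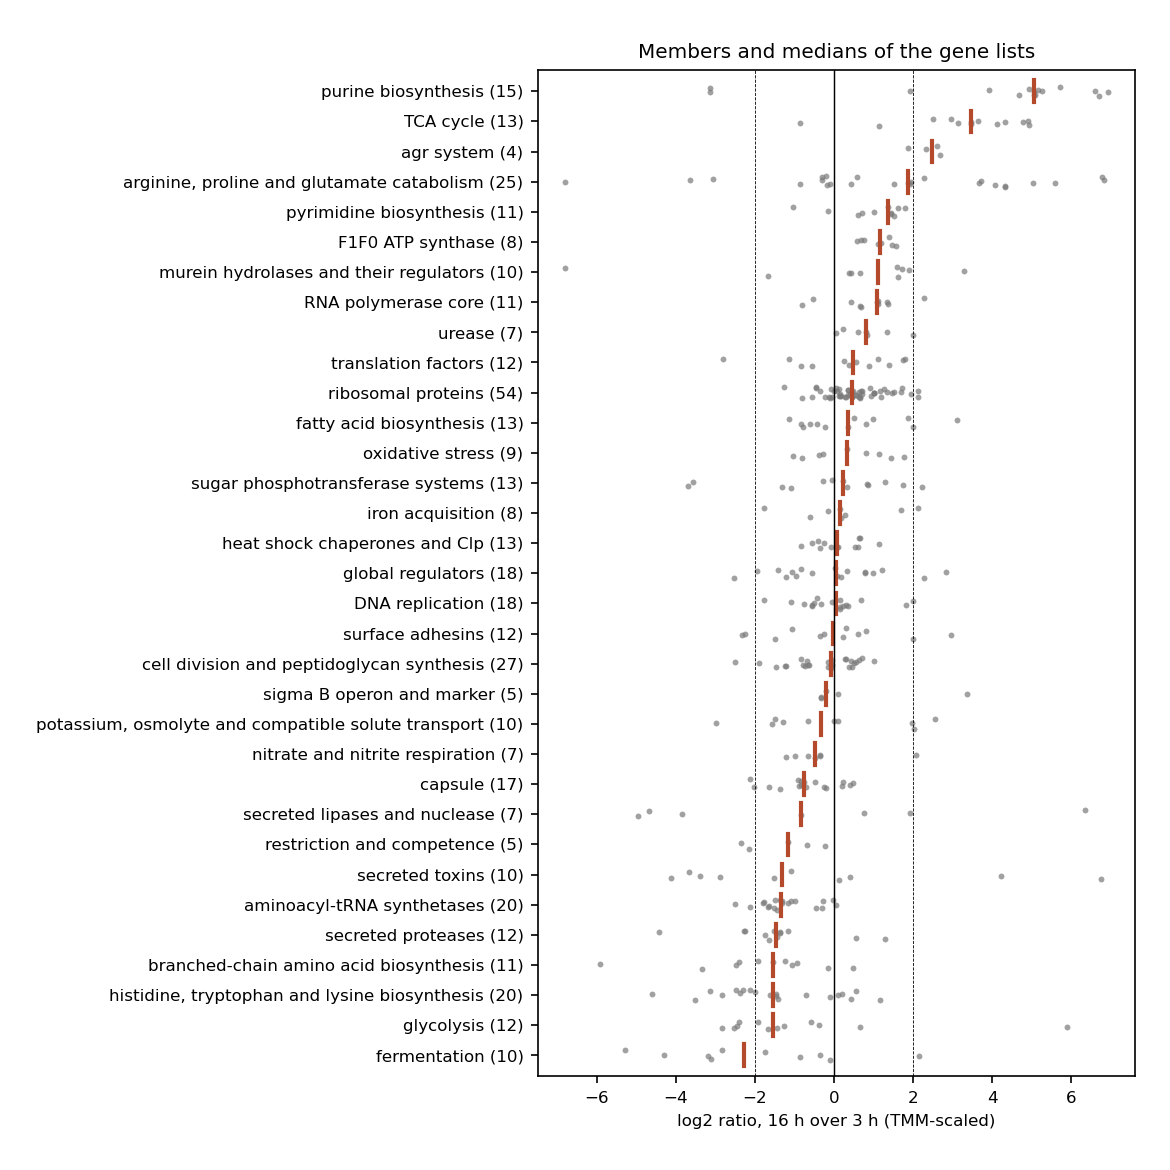
Log2 ratios, 16 h over 3 h in TMM scaling (x axis), of the members of the 33 gene lists with at least 3 measured members (y axis, number of members in brackets). Grey points are genes, red bars are list medians, and dashed lines mark 4-fold. Purine synthesis and the TCA cycle lie highest, with medians of 5.05 and 3.45, and fermentation lowest, with -2.28; the medians of 14 lists changed sign under at least 1 other scaling, 13 of them in RPKM.

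Virulence genes were compared next. The 4 genes of the agr quorum-sensing system were all at least 2-fold higher at 16 h, and 3 of them at least 4-fold, with a median log2 ratio of 2.47 (1.11 in RPKM, percentile 97.3). These genes are neighbours that count as 1 run (2.37), so the percentile compares 1 unit with random lists of 4 single genes. agrA, the response regulator, was 6.46-fold higher (6.33 to 6.60), agrB 6.11-fold (5.94 to 6.28), agrC 5.001-fold (4.92 to 5.08) and agrD 3.66-fold (3.43 to 3.90). In the authors' deposited table agrA, agrB, agrC and agrD were 2.24-fold, 2.60-fold, 1.78-fold and 1.75-fold higher, so none had a 4-fold difference there. The small RNA beside agrB (2146191 to 2146741), the place of RNAIII, the effector RNA of agr, was 12.8-fold higher (12.7 to 12.9), but 1.68-fold in the authors' deposited table. PSMa (476575 to 477063), the row of the alpha phenol-soluble modulins, was 18.6-fold higher (18.3 to 18.9), with 125535 reads at 16 h, and 4.71-fold higher in the authors' deposited table.

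Other secreted proteins differed in both directions. Among 10 toxin genes, hlgA and PSMa were at least 4-fold higher, 4 were at least 4-fold lower, and the median was -1.31 (percentile 1.05). The Panton-Valentine leukocidin genes lukS-PV and lukF-PV were 17.4-fold (15.7 to 19.3) and 12.7-fold (11.6 to 14.0) lower, and the leukocidin genes lukD and lukE had log2 ratios of -3.39 and -2.88. These pairs are neighbours, and with each run of neighbouring genes counted once the toxin median was 0.26. Of 12 genes in the protease list, 10 were at least 2-fold lower and 3 at least 4-fold lower (median -1.47, percentile 0.31). aur, for aureolysin, was 21.6-fold lower (16.4 to 29.1), and splA and splB, for serine proteases, were 4.86-fold and 4.79-fold lower. The 2 members above 0 in TMM scaling, scpA and scpB, are neighbours whose symbols also denote chromosome segregation proteins; the log2 ratios of both, 0.56 and 1.28, are below 0 in RPKM. The list of lipases, nuclease and other secreted enzymes had 1 of 7 members at least 4-fold higher, lip, and 3 at least 4-fold lower, with a median of -0.83 (percentile 11.5). These 3 were plc, the nuclease locus nuc at 866215, 25.6-fold lower (22.2 to 29.7), and the staphylokinase gene sak, 14.3-fold lower (10.4 to 20.1).

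Surface and envelope genes were mixed. Among 12 surface adhesin genes the median was -0.02, which became 0.02 with coding genes centred at 0. clfA, for clumping factor A, was 7.795-fold higher (7.61 to 7.98; 4.45-fold in the authors' deposited table), while clfB, for clumping factor B, and sbi, for an immunoglobulin-binding protein, were 5.001-fold and 4.78-fold lower. The 17 capsule genes had a median of -0.75 (percentile 16.5), with cap5A and cap5C 4.34-fold and 4.09-fold lower at 14 reads each at 16 h (3.69-fold and 3.51-fold in the authors' deposited table). The 10 murein hydrolase genes and regulators had a median of 1.12 in TMM scaling (percentile 98.6), 0.54 with each run of neighbouring genes counted once and -0.23 in RPKM; beside cidA, the lowest, the ssaA locus at 2415199 was 9.79-fold higher, although it lies inside a small RNA row. crtN and crtM, of staphyloxanthin synthesis, were 8.37-fold (7.21 to 9.74) and 6.36-fold (5.06 to 8.03) higher. Of the ica biofilm genes, icaC alone passed the read minimum, with 36 and 8 reads and a ratio whose interval, 0.234 to 1.27, includes 1.

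Regulators and stress genes had medians near 0. The 18 global regulators had a median of 0.06, a mean of -0.06 and medians of -0.20 in the authors' normalized values and -1.29 in RPKM. sarA, an activator of agr, was 7.14-fold higher (6.65 to 7.66; 4.38-fold in the authors' deposited table), and malR was 4.85-fold higher. sarX was 5.79-fold lower (2.56 to 16.2), on 6 reads at 16 h. rot, codY and ccpA had log2 ratios of 0.78, 0.77 and 0.33, which are below 0 in RPKM. Under the fixed rule mgrA was also to be given, but no row of the tables used here has that symbol. Of the 5 genes of the sigma B list, asp23, a marker of that sigma factor, was 10.3-fold higher (10.02 to 10.7; 4.61-fold in the authors' deposited table), whereas rpoF, the symbol in the table for the sigma factor gene beside rsbW, was 1.25-fold lower (1.15 to 1.35). The median of that list was -0.21 and its mean 0.52, and with its neighbouring genes counted once the median was 1.59. The 13 heat shock and Clp genes had a median of 0.07 (-0.15 in the authors' normalized values, -1.29 in RPKM), none of them differing by 4-fold, and the 9 oxidative stress genes one of 0.33 (-1.03 in RPKM), with dps 3.43-fold higher.

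Lists of transport and related genes split as well. Their members were matched by symbol, so not every member need encode a transporter. The 13 genes in the sugar phosphotransferase list had a median of 0.23 (-0.06 in the authors' normalized values, -1.12 in RPKM) and a mean of -0.19. In that list the fructose genes fruB and fruA were 13.0-fold (9.66 to 17.9) and 11.8-fold (10.1 to 13.8) lower. The mannitol gene mtlA was 4.71-fold higher (3.87 to 5.74). Of 10 genes for potassium and osmolytes (median -0.33, or 0.91 with each run of neighbours counted once), opuCa was 7.85-fold lower (6.49 to 9.59), while betB and opuD were 5.86-fold and 4.03-fold higher. The 8 iron acquisition genes had a median of 0.16 (-1.19 in RPKM), with feoB 4.37-fold higher on 18 and 30 reads. The 5 restriction and competence genes had a median of -1.16 (percentile 9.39); the hsdM loci at 457496 and 1936836 were 5.11-fold and 4.47-fold lower (4.64-fold and 3.46-fold in the authors' deposited table), but from 32% to 45% of their reads mapped to 1 place, so these values are uncertain. lacE and lacG, the measured members of the lactose list, had log2 ratios of 0.85 and 0.36 (below 0 in RPKM), with intervals of the ratio that include 1.

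The second comparison concerned small RNAs. Of 232 small RNAs with at least 20 reads, 49 were at least 4-fold higher at 16 h, 33 were counted as at least 4-fold lower, of which 3 had no read at 16 h, and 150 lay between. With equal coding totals the numbers were 38 and 46, with equal totals of all rows 35 and 55, and with the deposited RPKM 26 and 77. The highest ratio belonged to SAUSA300s046 (2430520 to 2430663), with 48 and 3350 reads, 183-fold higher (138 to 248). In the authors' deposited table it was 102-fold higher, and those near treR and aspS, named next, 35.01-fold and 19.7-fold. A small RNA 56 nt from treR (508155 to 508441) was 104-fold higher (98.3 to 111), one 248 nt from chs (2086588 to 2086647) 81.6-fold (52.9 to 133), and one 64 nt from aspS (1735802 to 1736040) 66.4-fold (64.1 to 68.8). The next, at 887272 to 887341 and at 442301 to 442398, were 35.6-fold (20.7 to 66.3) and 29.97-fold (21.9 to 41.95) higher. The former overlaps the coding row SAUSA300_0808.

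On the lower side, SAUSA300s171 (282760 to 282897), with 24372 and 235 reads, was 39.6-fold lower (34.8 to 45.2; 141-fold in the authors' deposited table). It lies 173 nt from the coding row that held the most reads at 3 h (283071 to 283880). A small RNA at 870085 to 870734, which overlaps the coding rows SAUSA300_0781 and SAUSA300_0782, had 291 and 3 reads and was 37.0-fold lower (12.5 to 181). One at 436139 to 436242, 229 nt from xpt, was 35.4-fold lower (18.6 to 77.7). Another 3 had no read at 16 h. Against a floor of 3 reads in that library, the one at 228412 to 228796 was at least 4.71-fold lower, that at 2665078 to 2665184 at least 3.56-fold lower and that at 2539602 to 2539971 at least 3.31-fold lower. With this floor the last 2 do not reach 4-fold, which leaves 31 small RNAs at least 4-fold lower. The row with the most reads at 16 h, at 2499822 to 2501038, had 58917 and 513644 reads. It was 22.8-fold higher (22.6 to 23.0), and 4.78-fold in the authors' deposited table. It overlaps the coding row SAUSA300_2325, and the use of strand is not given, so its reads may not all be of a small RNA. The other rows with the most reads, at 1502013 to 1502445 and at 690548 to 691421, were 12.2-fold (11.97 to 12.5) and 5.11-fold (5.03 to 5.19) higher, but 3.45-fold and 1.47-fold in the authors' deposited table.

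**Figure D3:**
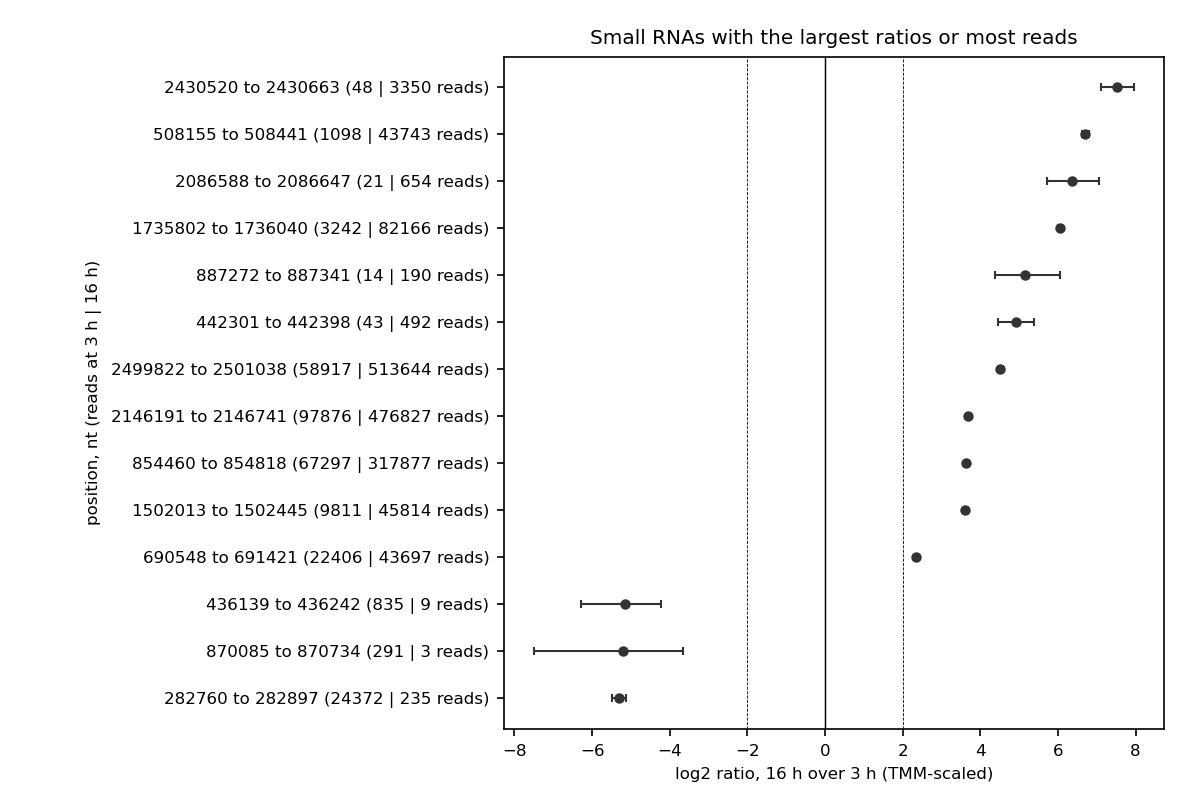
Log2 ratios, 16 h over 3 h in TMM scaling (x axis), of the small RNAs with the largest ratios or the most reads, by position (y axis) with the reads at 3 h and 16 h. Bars are exact 95% binomial intervals, which cover counting error only, and dashed lines mark 4-fold. The 3 small RNAs with no read at 16 h are not drawn, and the RNAs shown span ratios from 39.6-fold lower to 183-fold higher.

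The third comparison was of RNA classes. Of the mapped reads of the gene table, coding rows held 86.77% at 3 h and 48.83% at 16 h. The reads of the small RNA table were equal to 10.01% and 43.28% of the same mapped reads. The tables were made separately and share bases, so these shares were not added. Of the reads in the rows of the gene table alone, coding rows held 95.4% at 3 h and 79.9% at 16 h. Rows shorter than 100 nt without a symbol, which have the length of transfer RNAs but are not marked as such in the table, held 3.64% (3.62 to 3.66) and 13.0% (13.0 to 13.1). ssrA (854460 to 854818), the transfer-messenger RNA that rescues stalled ribosomes, held 0.980% (0.969 to 0.990) and 7.09% (7.06 to 7.12). Of the reads of the short rows 46.6% at 3 h and 25.5% at 16 h mapped to 1 place, and of those of ssrA none did, so these shares depend on how reads were counted. For the small RNA row at the position of ssrA, counted separately, 100% and 99.96% of reads did, so ssrA lacked such reads only in the gene table. Among reads that mapped to 1 place the short rows held 1.75% and 4.003%, and of summed RPKM they held 25.7% and 57.5%, while coding rows held 72.7% and 35.8% of summed RPKM. The small RNA row at the position of ssrA was 12.4-fold higher at 16 h (12.3 to 12.5), but 1.93-fold in the authors' deposited table. The 16 ribosomal RNA rows held 28 and 26 reads. Of 51 short rows past the read minimum, 31 were at least 4-fold higher at 16 h and none was 4-fold lower, with a median log2 ratio of 2.57 (1.22 in RPKM).

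The rows with the most reads differed between the libraries. At 3 h they were an 810-nt row (283071 to 283880) with 95920 reads, a 1014-nt row (842281 to 843294) with 59178, gap (843347 to 844357) with 50059, the DNA-binding protein gene hup with 45738 and the terminal oxidase gene qoxB with 44822. At 16 h they were ssrA, PSMa, a 2073-nt row (372415 to 374487) with 116554 reads, agrC with 44092 and qoxB with 40611. Across the 2390 coding genes, log2 CPM of the 2 libraries had a Pearson r of 0.744 and a Spearman rho of 0.756. These are correlations across genes, which are not independent replicates, so no p is given.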

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

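Alternatives with unique reads and without coding genes that lie 50% or more inside small RNA rows were chosen after the data were seen; the others were planned. With 1 library per group none could be left out. Against 212 coding genes at least 4-fold higher and 296 lower, equal coding totals gave 133 higher, equal totals of all rows gave 110 and 521, the deposited RPKM 83 and 833, a 2-fold threshold 512 and 629, and an 8-fold threshold 99 and 116. Against 49 small RNAs higher and 33 lower (31 with the floor for rows with no read), RPKM gave 26 and 77, 2-fold 84 and 62, and 8-fold 32 and 18; the number lower was 55 with equal totals of the gene table, 55 with no read minimum and 21 with a minimum of 100 reads. The other counts stayed within 1.5 times, such as 205 and 266 coding genes from the normalized fold changes in the authors' deposited table. Of 33 gene lists, 8 had a median at least 2-fold higher and 8 at least 2-fold lower. The number higher was 4 with equal coding totals, 4 with equal totals of the gene table, 3 in RPKM and 5 in the authors' normalized fold changes, and the number lower was 21 in RPKM. The scalings with fixed totals and RPKM move every gene alike, which by construction sets these differences; the cause of the others was not tested.

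Medians of lists that were at least 2-fold from 1 changed sign in 4 cases. In RPKM RNA polymerase came to -0.28, ATP synthase to -0.20 and murein hydrolases to -0.23, and secreted toxins came to 0.26 with each run of neighbours counted once. Over 194 single genes, small RNAs and list medians with 1457 alternatives, 824 values stayed within the counting interval and 633 did not. Of all values, 70 had another sign than the main value, 24 of them from single genes or small RNAs and 46 from list medians, and 28 of the 70 were in RPKM. Among single genes at least 2-fold higher, 6 were below 0 in RPKM; none with a 4-fold difference changed sign. The share of the gene table in coding rows was 72.7% and 35.8% of summed RPKM at 3 h and 16 h, and 98.3% and 96.0% of unique reads. For the short rows it was 25.7% and 57.5%, and 1.75% and 4.003%; for ssrA it was 1.61% and 6.70%, and 0% of unique reads in both libraries. Pearson r across genes was 0.804 with no read minimum, 0.740 with 0.1 CPM added and 0.746 with 10 CPM added, and Spearman rho was 0.801 with no read minimum. Matching lists by product description was not run because the tables used here hold none, and a pseudocount of 10 does not apply to ratios of counts. Depth limited genes with few reads most, such as cidA, with an interval of 19.8 to 4402 around 111-fold.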

Other observations

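The groups of genes in this part and all tests were chosen after the values were seen. Neighbouring genes often differed in 1 direction. There were 26 runs of at least 4 neighbouring coding genes that were each at least 4-fold higher (9 runs) or lower (17 runs) at 16 h, together 131 genes. In 10000 shuffled gene orders the mean was 0.507 runs and the highest number 5. The longest run higher at 16 h had 12 genes from folD to purD (1058386 to 1070681), with a median log2 ratio of 5.12. putA was followed by ribH, ribBA, ribE and ribD, genes of riboflavin synthesis, in a run (1893797 to 1898232) with log2 ratios from 2.62 to 6.77. Among the lower runs, 7 genes without a symbol (195474 to 201632) had a median of -8.22, with members from -9.82 to -2.25. The run of xpt, pbuX, guaB and guaA (436472 to 441388) had a median of -3.85, and the small RNA 229 nt before it, 35.4-fold lower, had the same direction.

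Genes outside the fixed lists were grouped by the first 3 letters of their symbols, which gave 41 groups of at least 3 genes with 202 genes. Of 5 rib genes, 4 were at least 4-fold higher at 16 h, and of 6 glp genes 3 were, with glpF and glpK, for glycerol uptake and its phosphorylation, at log2 ratios of 4.87 and 3.85. Of 8 epi genes, whose symbols are those of lantibiotic synthesis and immunity, epiE, epiG, epiF and epiP had log2 ratios of 3.95, 3.77, 3.20 and 2.20, while epiA to epiD lay between 0.03 and 0.95 (below 0 in RPKM). Of 3 uvr genes, of nucleotide excision repair, uvrA and uvrB had log2 ratios of 2.22 and 2.34 and uvrC one of 0.69 (below 0 in RPKM). The 3 met genes metB, metE and metK were all lower, at -3.67, -2.74 and -2.70, and metE overlaps a small RNA row. Of 5 pan genes, of pantothenate synthesis, 3 were at least 4-fold lower. Of 5 glt genes, 3 were at least 4-fold lower, among them gltB and gltD, for glutamate synthase, at -3.24 and -2.65. The glt gene gltS was higher, at 2.23. The 4 qox genes, of a terminal oxidase, lay between 0.81 and 1.54, where values up to 1.34 are below 0 in RPKM, and the 4 dlt genes, of teichoic acid alanylation, between -1.10 and -0.65.

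Of 51 short rows without a symbol, 31 were at least 4-fold higher at 16 h and 20 were under 4-fold, 7 of them with a log2 ratio below 0; the median was 2.57. The 35 small RNAs under 100 nt had a median of 0.188 with an SD of 2.83, 9 of them at least 4-fold higher and 6 at least 4-fold lower. As a set they did not share the gain of the short rows, and the median of all small RNAs was 0.351. Their values were widely spread, with 1 library per time point, so a gain that reached only some short features stays open. Reads shared between copies are argued against as the whole cause by 9 of 19 short rows with at least 90% unique reads in both libraries that were still at least 4-fold higher. The median of these 19 rows was 1.96, and copies that share reads may count more than once among the 51. A difference in RNA recovery or size selection between the 2 preparations was not tested and, with 1 library each, cannot be separated from growth phase. A change in transfer RNA abundance in stationary phase may be a further explanation, likewise untested.

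The symbols ald, gap and rocD are each given to 2 loci that differed by at least 4-fold in opposite directions; rocD was 12.5-fold lower (5.96 to 31.4) at 215727 and 19.9-fold higher (18.4 to 21.6) at 937855. Reads shared between the copies are argued against, since the lowest share of their reads that mapped to 1 place was 99.88%. Among 50 such pairs of loci, 3 opposite pairs were found against a mean of 1.10 in random sets of 50 gene pairs, and a share of 0.0956 of random sets held as many, so chance pairing of strongly differing genes could account for the number. Opposite roles of the copies in exponential and stationary phase stay open.

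In RPKM most coding genes had ratios below 1, with a median log2 ratio of -1.39. A candidate explanation is that a few abundant RNAs took a larger part of the reads at 16 h, since 3 small RNA rows (at 2146191, 854460 and 2499822) held reads equal to 5.96% of the mapped reads at 3 h and 35.7% at 16 h. The 9 coding rows among the 5 with the most reads in either library held 11.2% and 20.9% of coding reads. With totals that leave out all non-coding rows and these 9 genes the median was -0.391, and with coding totals alone it was -0.56. A lower amount of messenger RNA per cell at 16 h was not measured and stays open.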
